A study of Rattus norvegicus with 6 samples.

How the data were processed

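Total RNA from rat spinal cord was pooled from 5 animals per combination of genotype and stage, and 750 ng of each pool was labelled with biotin for 1 Illumina BeadChip array, per the labels' protocols. The labels give 6 arrays, 3 of SOD1 G93A rats and 3 of WT littermates, with 1 array each for the presymptomatic stage, disease onset and end stage. All 6 samples are labelled with an age of 10 weeks, which the study's design text gives for the presymptomatic stage alone, so ages were not used. Samples were grouped by the genotype and stage in the labels.

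Both deposited tables were used. The first is named non-normalized and holds a linear intensity and a detection p-value per probe and array, as the authors deposited them. Its deposited intensity values were already background-subtracted (values below 0 occur) and scaled, since the means of the 6 arrays lay between 330.9 and 332.4. The detection p-value was deposited beside each intensity and comes from BeadStudio 3.2.6, the software named in the submitters' processing notes. The second table holds the authors' deposited normalized intensity, which rises with the first table's values within each array (rank correlation 1.0). Its scale is linear, its normalization method is not given in the sources used here, and its medians per array ran from 4.41 to 19.8. It served as an alternative. No other column of either table was left out.

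Gene names came from the platform annotation supplied with the series matrix, in which 13192 of the 22226 probes have exactly 1 gene symbol, 0 have several and 9034 are unnamed here. All named probes were also looked up by gene identifier in a RefSeq gene table of the GRCr8 assembly, which held 13151 of them and changed 0 symbols. No coordinates are given, because the files name no genome build.

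The deposited probe IDs were found to be out of order relative to the values in both tables. The test compared the detection of probes for sensory receptors, which spinal cord should largely lack, with that of ribosomal, respiratory chain and proteasome genes, under 5 orders of the IDs. The orders were those of the deposited table, the IDs sorted as text, sorted by number, reversed, and sorted by accession. Sorting as text gave shares of 1.37% and 88.6% whereas the other orders left the sensory share at 34.1% or more and the other share at 41.9% or less. The correlation across probes of level with class was 0.227 at this alignment, at most 0.0588 in size over 400 shifts of the sorted IDs against the values, 0.00186 as deposited and at most 0.0245 in size over 1000 random permutations. In 11 stretches of the table the sensory share ran from 0 to 3.26% and the other from 69.2 to 100%. Levels of the 206 genes with 2 probes correlated across genes with Spearman's rho = 0.22 after sorting and 0.02 as deposited. Only 1 probe has the same place in both orders. The sorted IDs were used throughout, and the pairing as deposited was kept as an alternative. The cause of the disorder is not known, and a reader who wants gene names should treat them as resting on this step.

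Values were normalized with limma 3.58.1 in R 4.3.3 by neqc, that is normexp background correction with noise parameters inferred from the detection p-values, an offset of 16, quantile normalization and log2. Because the deposited intensities were already background-subtracted, neqc inferred a large noise level, and the lowest normalized value was 6.62. A regression of intensity on the detection p between 0.05 and 0.95 put the noise SD at 6.52 to 8.46 intensity units with a mean of 1.15 to 1.68. Log2 differences of dim probes are therefore understated, and normexp with the regressed noise was added as an alternative. Probes were kept where the detection p was below 0.01 on at least 1 array (12711 probes, 8372 of them detected on all 6). For tables of genes the kept probe with the highest mean stood for its gene (8752 genes).

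With 1 pool per genotype and stage, 3 kinds of comparison were fixed before the data were examined. The genotype comparison used limma's lmFit and eBayes over 6 pools with stage as a block. The mutant pool of each stage was compared with the 3 WT pools, taken as replicates although they differ in age, and the lone mutant pool was assumed to vary as they do. The end-stage and presymptomatic mutant pools were compared in that same fit. Each fit had 2 residual degrees of freedom, all tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the kept probes with a threshold of 0.05. The adjusted p-values describe the spread between these pools. Stage-matched differences (mutant minus WT pool of the same stage) were counted where they reached 2-fold and the probe was detected on at least 1 of both arrays, without a test, and the pairs of WT pools were counted in the same way. Where a transcript was detected on only 1 of the arrays compared, its fold is given as a bound, the bright value less the higher of the dim value and the lowest normalized signal of a detected probe on that array.

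The 42 gene lists were also fixed before the data were examined, and 38 had at least 5 measured genes. They were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and adjusted over the lists. For each stage-matched difference the median of a list was also set among 10000 random lists of the same size matched on mean expression. Some genes stand in several lists.

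Genes were named by a rule fixed before the data were examined. It took Sod1 and Atf3, and for end stage and onset the 10 largest differences per direction among genes detected on both arrays whose mutant value lay outside the range of the 3 WT pools, with the 5 largest bounds per direction. It took 5 and 5 for the presymptomatic stage. For genotype across stages it took the 10 largest passing differences per direction or, where fewer than 5 pass, the 5 smallest p-values per direction. It took up to 4 members per list with the largest end-stage difference, and 5 passing genes per direction for end stage against the presymptomatic stage.

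The steps were tested on simulated data. Among 12711 simulated probes, 100 changed by 2-fold and 100 by 4-fold. In the end-stage comparison 66 and 89 of these were recovered, with 2 unchanged probes called, and in the genotype comparison 84 and 96, with 9 unchanged probes called. Recovery was 66 and 84 at onset, 63 and 84 at the presymptomatic stage and 53 and 80 for end stage against the presymptomatic stage. These figures take the spread of the WT pools as given. In the genotype comparison the simulated change was the same at all 3 stages, so its recovery does not hold for changes confined to some stages. Of 2 simulated lists of 40 genes, camera with the preset correlation gave the shifted one p = 6.58e-86 at end stage and the unshifted one p = 0.473. The simulated genes varied independently of each other. The simulation therefore cannot tell whether the preset correlation suits lists of real genes. Alternatives covered the background correction, the normalization, the filter on dim probes, the variance prior, each pool left out in turn, the size threshold and the reference pool. Figures were drawn with matplotlib 3.10.9.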

Results

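Gene expression was measured on Illumina rat BeadChips in spinal cord of female Sprague-Dawley rats that carry a mutant superoxide dismutase gene (SOD1 G93A, a model of amyotrophic lateral sclerosis) and of their wild-type (WT) littermates. There were 6 arrays. Each held RNA pooled from 5 rats, so 30 rats entered the study, and each genotype was represented by 1 pool at a presymptomatic stage, 1 at disease onset and 1 at end stage. The number of arrays limits the precision, and no single combination of genotype and stage had a replicate. Between 9116 probes (presymptomatic mutant pool) and 10942 probes (presymptomatic WT pool) of 22226 were detected per array at a detection p below 0.01, and 12711 probes were detected on at least 1 array. The labels place the tissue in both the lumbar and the thoracic cord, so the segment is left open here.

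The probe names as deposited did not belong to the values beside them, and every gene name below rests on a reordering of the probe IDs. With the deposited pairing, 38.1% of 1242 probes for odorant, pheromone, taste and trace-amine receptors were detected on all 6 arrays, against 41.9% of 167 probes for ribosomal, respiratory chain and proteasome genes. With the same IDs sorted as text and set against the values in their row order, these shares were 1.37% (exact 95% interval 0.799 to 2.18%) and 88.6% (82.8 to 93%). Actb, which encodes cytoplasmic actin, had a mean WT intensity of 32.1 as deposited and 6275 after sorting, and the beta-globin gene Hbb went from 3.52 to 21350, both examples being chosen after their values were seen. The choice of order used probe levels only, with no comparison of mutant with WT. The counts of probes below do not depend on it, except those of probes without a gene name.

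**Figure D1:**
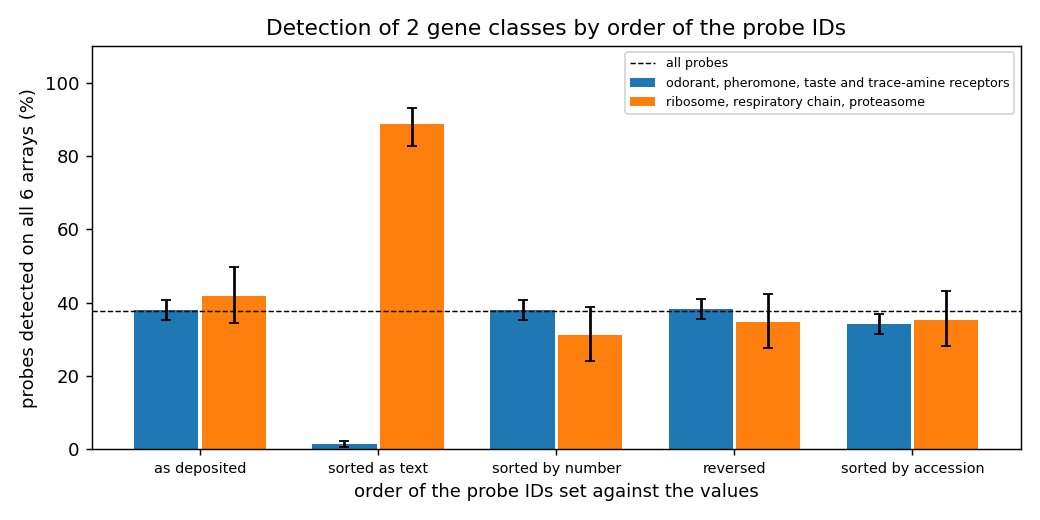
Share of probes detected on all 6 arrays (vertical axis, percent, with exact 95% binomial intervals) for 2 classes of genes under 5 orders of the probe IDs (horizontal axis), with the share of all probes dashed at 37.7%. The classes part only with the IDs sorted as text, at 1.37% for sensory receptors and 88.6% for ribosomal, respiratory chain and proteasome genes.

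The end-stage comparison asked which transcripts differ in the cord once the disease is advanced. The transcripts with the largest excess in the end-stage mutant pool over its WT pool were Ngfr, the p75 neurotrophin receptor (21.4-fold), Cd68, a lysosomal protein of macrophages and microglia (21.3-fold), the interferon-induced Ifitm1 (19.9-fold) and Lgals3, which encodes galectin-3 (14.7-fold). They were followed by S100a11 (10.4-fold), the chemokine genes Cxcl9 (3.63 on the log2 scale) and Cxcl13 (9.99-fold), the phagocyte oxidase subunit gene Ncf1 (8.47-fold), Cthrc1 (8.30-fold), a gene of the extracellular matrix, and Gas7 (8.10-fold). Atf3, a transcription factor of the stress and nerve injury response, was 6.88-fold higher. Among transcripts detected in the mutant pool and not in its WT pool, the excess was at least 3.55-fold for Thbs2, at least 3.02-fold for Sectm1b, at least 2.69-fold for Plbd1, at least 2.63-fold for the macrophage elastase gene Mmp12 and at least 2.57-fold for Galnt3.

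On the other side, Slc18a3, the vesicular acetylcholine transporter of motor neurons, was 4.27-fold lower in the end-stage mutant pool, the heavy neurofilament gene Nefh 3.92-fold lower, the calcium-binding protein gene Cabp1 3.90-fold lower, the glycolytic enzyme gene Pkm 3.67-fold lower and Hagh 3.46-fold lower. The other 5 of the 10 transcripts with the largest deficit were genes of skeletal muscle. Tnnc2 was 9.33-fold lower, Ckm 8.80-fold, Acta1 4.42-fold, Actn3 4.11-fold and Myl11 4.02-fold, and the muscle list as a whole was highest in the end-stage WT pool (median log2 intensity 8.61, against 7.31 and 7.99 in the presymptomatic and onset WT pools). Transcripts detected in the WT pool and not in the mutant pool were all close to background, with deficits of at least 1.32-fold (Yif1b), 1.20-fold (Chodl, a marker of fast motor neurons), 1.19-fold (Lyrm9), 1.16-fold (Tspan7) and 1.14-fold (Mapk10).

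In all, 292 of 7942 genes were at least 2-fold higher and 148 at least 2-fold lower in the end-stage mutant than in the end-stage WT pool, a balance that turned with a 75th-percentile shift (225 higher, 381 lower). Counted the same way, the 3 pairs of WT pools differed in 47, 59 and 61 genes. These stage-matched differences set 1 array against 1 and have no replicate check. Against the spread of the 3 WT pools, limma called 213 of 12711 probes at an adjusted p below 0.05, 166 higher and 47 lower, of which 37 probes carried no gene name. Named genes that rose in this test included Cd68 (log2 difference 4.47 ± 0.17, SE, adjusted p = 0.0287), Ifitm1 (4.14 ± 0.16, adjusted p = 0.0288), Ngfr (4.27 ± 0.32, adjusted p = 0.0477), Ncf1, Cthrc1 and Atf3 (2.77 ± 0.08, adjusted p = 0.0286). Pkm fell by 1.96 on the log2 scale (adjusted p = 0.0310), whereas Lgals3 (adjusted p = 0.0600), Cxcl13 (0.0519), Slc18a3 (0.193), Nefh (0.215) and the muscle genes did not pass. The call rests on a lone mutant pool taken to vary as the WT pools do, and the count was 2 with the deposited normalized values and 1056 (446 higher, 610 lower) with a 75th-percentile shift in place of quantile normalization. With any 1 WT pool left out, which leaves 1 residual degree of freedom, 0 probes passed (smallest adjusted p = 0.130 to 0.182) while Atf3 stood at 2.73 to 2.81. Differences of dim transcripts are understated on the scale used, since Atf3 reached 4.21 with a lower estimate of the noise, chosen after seeing the data.

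**Figure D2:**
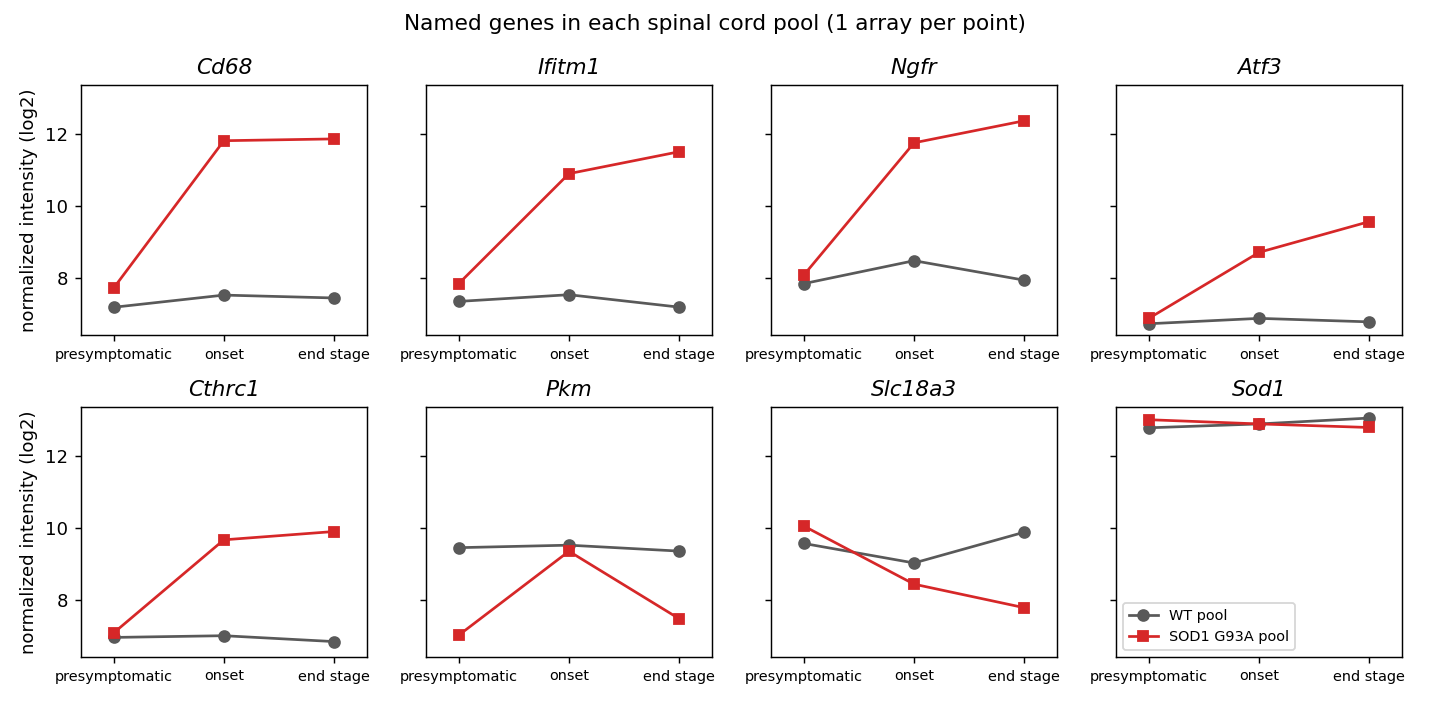
Normalized log2 intensity (vertical axis) of 8 named genes at the presymptomatic stage, onset and end stage (horizontal axis), with 1 point per pool, grey circles for WT and red squares for SOD1 G93A. Cd68, Ifitm1, Ngfr, Atf3 and Cthrc1 were above all 3 WT pools at onset and end stage, Slc18a3 was below them at both, Pkm stood at a log2 difference of −2.43 from its WT pool before symptoms and −1.88 at end stage, and Sod1 differed little.

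Grouped by the lists fixed before the data were examined, the end-stage pool was higher in genes of microglia, phagocytes and innate immunity. The list p-values of each stage also rest on a lone mutant pool and do not measure the spread between mutant pools. All 13 measured complement genes were higher, 10 of them at least 2-fold (median log2 difference 1.94, adjusted p = 1.87e-08 by limma's camera with a preset correlation), led by Cfd (2.49), C4b (2.25), Serping1 (2.22) and C1qc (2.15). Of 22 genes for phagocyte receptors and adaptors, all were higher and 10 were at least 2-fold higher (median 0.80, adjusted p = 6.71e-12), among them Arpc1b (2.11), Cyba (2.02) and Cd53 (1.65). The disease-associated microglia list had a median of 0.88 over 19 genes (adjusted p = 1.07e-09), with Trem2 at 2.21 and its adaptor gene Tyrobp at 2.15. The homeostatic microglia list had a median of 0.06 over 9 genes (adjusted p = 0.00435), inside the central 95% of random lists (−0.10 to 0.09), in which Fcrl2 (2.15) and Aif1 (1.40) stood beside Olfml3 (0.66) and Itgam (0.39). Interferon response genes had a median of 1.22 over 16 genes (adjusted p = 2.35e-08), with Gbp2 at 2.69 and Cxcl11 at 2.45. Antigen presentation genes had a median of 0.52 over 19 (adjusted p = 1.35e-06), led by the invariant chain gene Cd74 (2.14), RT1-DMb (1.89), Psmb8 (1.68) and RT1-A2 (1.47). The cytokine and chemokine list had a median of 0.20 over 21 genes (adjusted p = 6.46e-06), with Il33 at 1.71, Il18 at 1.57 and Cxcl10 at 1.39. With the lower noise estimate the medians were 1.52 for disease-associated microglia, 1.23 for phagocyte, 0.92 for cytokine and 0.58 for homeostatic microglia genes. None of these 7 lists passed with an estimated correlation (adjusted p = 0.267 to 0.360 with an estimated correlation).

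Reactive astrocyte genes were also higher at end stage, in all 22 measured members (median 1.0, adjusted p = 6.26e-10), with Timp1 at 2.90, Cp at 1.96 and S100a4 at 1.82, whereas the general astrocyte list was lower (median −0.43 over 13 genes, adjusted p = 0.00109), with Gjb6 at −0.94, the glutamate transporter gene Slc1a2 at −0.77, S100b at −0.67 and Mlc1 at −0.60. Extracellular matrix genes had a median of 1.03 over 25 (adjusted p = 9.63e-07), with Col5a2 at 2.13, Col1a1 at 2.02 and Col3a1 at 1.86, and the meningeal and fibroblast list moved with them (median 1.15 over 14 genes, adjusted p = 0.0112; Aldh1a2 1.70, Mgp 1.64). Against all 3 WT pools, the contrast camera tests, the medians of the matrix and meningeal lists were 0.63 and 0.66. Immediate-early genes had a median of 0.84 over 19 (adjusted p = 4.19e-07), with Junb at 2.36, Zfp36 at 1.81, Jun at 1.60 and Klf6 at 1.49. The lysosome and autophagy list had a median of 0.49 over 32 genes (adjusted p = 1.34e-05), with Ctsd at 2.14, Gusb at 1.96 and Ctsk at 1.80. Also passing as higher in camera were cell cycle genes (0.15 over 24, adjusted p = 1.23e-05; Ccnd1 2.47, Tubb5 1.10), apoptosis and p53 genes (0.11 over 20, adjusted p = 3.74e-04; Gadd45a 2.44, Tnfrsf1a 1.37, Casp1 1.17, Ccng1 1.12), cytosolic ribosomal genes (0.21 over 51, adjusted p = 2.14e-04; Rps13 1.17, Rpl30 0.88), lipid efflux genes (0.24 over 17, adjusted p = 0.00435; Apoc1 2.82, Plin2 1.84, Pltp 1.52, Scd −1.56) and nerve injury genes (0.02 over 23, adjusted p = 0.0114; Atf3 2.78, Tnfrsf12a 1.90). The nerve injury median lay inside the central 95% of random lists (−0.08 to 0.06), with 13 genes higher and 10 lower, and the lipid efflux median against all 3 WT pools was 0.12. The order of these medians depends on the scale, since the lower noise estimate gave 0.97 for cell cycle, 0.74 for apoptosis, 0.51 for lipid efflux and 0.12 for nerve injury genes, and a 75th-percentile shift gave 0.02 for ribosomal genes. These lists did not pass with an estimated correlation either (adjusted p = 0.267 to 0.392 with an estimated correlation).

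Genes of neurons, myelin and energy metabolism were lower. All 45 measured respiratory chain genes were lower in the end-stage mutant pool (median −0.38, adjusted p = 8.02e-11), with Ndufa8 at −1.25, Ndufb3 at −0.96, Ndufb8 at −0.92 and Ndufs7 at −0.81. Of 18 cholesterol synthesis genes 17 were lower (median −0.69, adjusted p = 9.63e-07), among them Fdft1 (−1.5), Insig1 (−1.34), Idi1 (−1.09) and Sqle (−1.07). Oligodendrocyte and myelin genes had a median of −0.51 over 22 (adjusted p = 4.09e-05), with Bcas1 at −1.34, Mbp at −1.27, the carbonic anhydrase gene Car2 at −1.26 and Nkx6-2 at −1.22. Of these, Car2 (adjusted p = 0.0286) and Nkx6-2 (adjusted p = 0.0434) passed as single genes. Neuron and synapse genes were lower in 26 of 28 (median −0.30, adjusted p = 1.71e-05; Kcnc1 −1.17, Thy1 −1.15, Stmn2 −0.95, Vamp1 −0.91), inhibitory neuron genes in 13 of 14 (median −0.48, adjusted p = 7.22e-04; Calb2 −1.38, Slc32a1 −1.27, Pvalb −1.10, Slc6a5 −0.84) and glutamate receptor and transporter genes in 10 of 13 (median −0.30, adjusted p = 0.0221; Grin1 −0.89, Slc17a6 −0.84, Grin2c −0.59). The motor neuron list did not pass (median −0.05 over 16 genes, adjusted p = 0.0803), although Slc18a3, Nefh (−1.97) and Nefl (−1.11) were among its members. The muscle list was lower too (median −1.34 over 12 genes, or −0.82 against all 3 WT pools, adjusted p = 0.00334). None of these lists passed with an estimated correlation (adjusted p = 0.267 to 0.506 with an estimated correlation). A 75th-percentile shift moved the median of all genes at end stage from −0.01 to 0.16 and that of the motor neuron list to 0.20, though the latter was −0.46 with the lower noise estimate, −0.53 without background correction, −0.23 at offset 50 and −0.20 with the deposited values. With that shift the respiratory chain (−0.66), cholesterol (−0.99), myelin (−0.67) and neuron lists (−0.50) stayed lower, and with the lower noise estimate the neuron and glutamate lists stood at −0.59 and −0.52.

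Counted gene by gene and adjusted over the list alone, 15 of the 22 phagocyte genes, 14 lysosomal, 12 disease-associated microglial, 12 interferon response, 11 complement, 11 reactive astrocyte and 11 immediate-early genes rose at end stage and 11 of 45 respiratory chain and 3 lysosomal genes fell. Over all probes tested the first 8 of these counts were 5, 3, 5, 4, 2, 6, 1 and 1. Of 38 lists tested, 27 passed with the preset correlation, 18 higher and 9 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.267 with an estimated correlation). With the probe IDs as deposited, 0 of the lists passed.

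**Figure D3:**
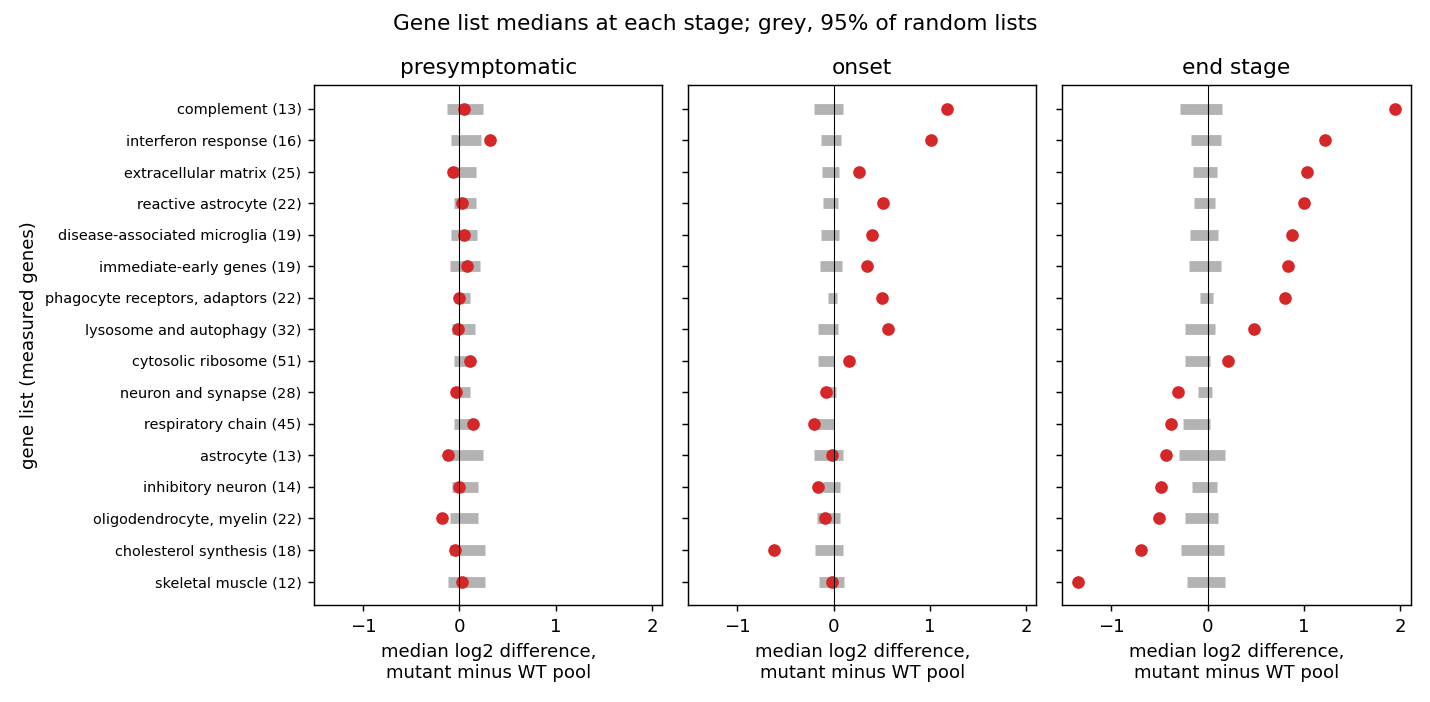
Median log2 difference of the mutant from the stage-matched WT pool (horizontal axes) for 16 gene lists (vertical axis, number of measured genes in brackets) at the 3 stages, with red points for the lists and grey bars for the central 95% of 10000 random lists matched on expression. At end stage the points run from 1.94 for complement to −1.34 for skeletal muscle, and at the presymptomatic stage from 0.32 for the interferon response to −0.18 for myelin, which turns to 0.01 with a 75th-percentile shift.

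The onset comparison addressed the first stage with symptoms. The transcripts in excess were largely those of end stage. Cd68 was 19.5-fold higher in the onset mutant pool than in its WT pool, Ifitm1 10.3-fold, Ngfr 9.65-fold, Ncf1 8.27-fold, Lgals3 8.07-fold, Cxcl13 8.0-fold, Cxcl9 6.93-fold, Cthrc1 6.32-fold, the folate receptor gene Folr2 6.15-fold and Trem2 5.63-fold. Atf3 was 3.56-fold higher. Transcripts seen in the mutant pool alone were at least 1.45-fold (Mmp12), 1.40-fold (Sectm1b), 1.35-fold (Lrrc15), 1.27-fold (Lpar3) and 1.26-fold (Cd8a, of cytotoxic T cells) higher. The deficits were smaller. They included the lipid metabolism genes Scd (2.45-fold), Acsl1 (2.31-fold), Lpl (2.24-fold), Idi1 (2.22-fold) and Tm7sf2 (2.06-fold), along with Ywhag (2.36-fold), Abcg2 (2.21-fold), Cdkn1b (2.18-fold), Rgs4 (2.07-fold) and Mdga2 (2.06-fold). Transcripts seen in the onset WT pool alone were at least 1.5-fold (Chodl), 1.32-fold (Scn10a), 1.10-fold (Cryba2), 1.09-fold (Inpp4b) and 1.08-fold (Hemgn) lower in the mutant pool.

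At onset 149 of 7940 genes were at least 2-fold higher and 15 at least 2-fold lower, or 164 in all, against 317 with the end-stage and 363 with the presymptomatic WT pool as the reference. Of the 149, 125 were also at least 2-fold higher at end stage, where 5.86 would be shared by independent lists of these sizes among 7424 genes. That number is a low estimate, since a 2-fold difference needs a level well above background at both stages. Both comparisons used separate arrays. Across these genes, which are not independent replicates, the stage-matched differences of the 2 stages correlated with Pearson's r = 0.66 and Spearman's rho = 0.48. In the limma test against the WT pools 0 of 12711 probes passed at onset (smallest adjusted p = 0.0644), with 1601 at an unadjusted p under 0.05. The count was 86 with the lower noise estimate and 241 with a trended, robust variance prior.

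By list, the onset pool was higher in complement (median 1.18, 8 of 13 genes at least 2-fold higher, adjusted p = 7.52e-09) and interferon response genes (1.01, 8 of 16, adjusted p = 7.31e-11), and in the lysosomal (0.57, adjusted p = 1.06e-08), reactive astrocyte (0.51, adjusted p = 1.39e-08), phagocyte (0.50, adjusted p = 3.29e-14), disease-associated microglia (0.40, adjusted p = 2.86e-10) and homeostatic microglia lists (0.33, adjusted p = 9.32e-06). With the lower noise estimate these medians were, in the same order, 1.43, 1.01, 0.60, 0.83, 1.30, 0.68 and 0.96. Cholesterol synthesis genes were lower (−0.62, adjusted p = 1.29e-05), as were respiratory chain genes (−0.20, adjusted p = 8.40e-08). None of these 9 lists passed in the other form of the test (adjusted p = 0.337 to 0.424 with an estimated correlation). The motor neuron list passed here (−0.06, or −0.42 with the lower noise estimate, adjusted p = 0.0169) and the myelin list did not (−0.09, or −0.27 against all 3 WT pools, adjusted p = 0.0633). In total 22 lists passed at onset, 16 higher and 6 lower, and 0 with an estimated correlation (smallest adjusted p = 0.337 with an estimated correlation). Whether a list differed between onset and end stage was not tested.

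The presymptomatic comparison asked what precedes symptoms. The largest excesses were modest, in Scaf1 (2.95-fold), Cuedc1 (2.56-fold), Agtrap (2.45-fold), Mrpl23 (2.38-fold) and Reep6 (2.31-fold). The deficits were larger. Capns1 was 11.6-fold lower in the presymptomatic mutant pool than in its WT pool, the Golgi protein gene Glg1 stood at −3.32 on the log2 scale, Nefh 9.99-fold lower, Cox7a2l 8.67-fold lower and the ribosomal protein gene Rpl13a 8.55-fold lower. Transcripts no longer detected in that mutant pool included Timp2 (at least 5.69-fold lower), Ppp2r5b (4.65-fold), Ddx23 (4.47-fold), Rps2 (4.23-fold) and Hcn2 (3.82-fold). Those detected only in the mutant pool of the pair stayed near background, with excesses of at least 1.20-fold (Ctf1), 1.14-fold (Artn), 1.13-fold (Fem1c), 1.10-fold (Gapdhs) and 1.10-fold (Gabrd). Markers that led at the later stages were close to WT here, with Cd68 at 0.53, Ngfr at 0.24, Atf3 at 0.15 and Lgals3 at 0.13 on the log2 scale.

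Before symptoms 30 of 7892 genes were at least 2-fold higher and 208 at least 2-fold lower, or 238 in all, and 141 with the end-stage WT pool as the reference. The array of this mutant pool had the fewest detected probes, and the same 208 genes had a median log2 difference of −0.25 between the end-stage and the onset WT pool and of −0.35 between the end-stage mutant and its WT pool. Of the 148 genes at least 2-fold lower at end stage, 132 were lower by any amount at onset (median −0.34) and 90 before symptoms (median −0.14). At least 2-fold lower were 3 of the 148 at onset, where only 15 genes reached that size, and 31 before symptoms, where 208 did. Pkm and Nefh were among the 31. Independent lists of these sizes would share 0.299 between end stage and onset, among 7424 genes. Between end stage and the presymptomatic stage they would share 4.20, among 7326 genes. Both numbers are low estimates, since a 2-fold deficit needs a level well above background. In the limma test 0 probes passed (smallest adjusted p = 0.119), with 1786 at an unadjusted p under 0.05, and 258 passed with the lower noise estimate, 256 of them lower. None of the 38 lists passed, with either correlation (smallest adjusted p = 0.213 with the preset and 0.942 with an estimated correlation). Complement (median 0.04), phagocyte (0.00) and disease-associated microglia genes (0.04) had presymptomatic medians near 0, and the interferon response list stood at 0.32, or 0.16 against all 3 WT pools and 0.60 with the lower noise estimate. Its stage-matched median lay at percentile 99.7 of random lists, with the respiratory chain (99.5) and ependyma lists (99.8) about as far up. The neutrophil (0.03) and myelin lists (0.19) were about as far down, and the oligodendrocyte precursor list less so (1.48). These percentiles rest on the stage-matched pair alone, 1 array against 1, and not on all 3 WT pools. With a 75th-percentile shift, which moved the median of all genes from 0.02 to 0.14, 5 lists passed, and 5 also passed with the deposited normalized values.

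To ask what separates end stage from the presymptomatic stage within the mutants, the 2 mutant pools were set against each other in the same model. No probe passed (0 of 12711 in limma, smallest adjusted p = 0.0548, 2208 at an unadjusted p under 0.05), so no gene is named by this rule. The difference was 4.14 for Cd68, 3.42 for Ncf1, 2.81 for Cthrc1 and 2.68 for Atf3 on the log2 scale, each with that smallest adjusted p, and the stage-matched difference of differences was 3.88, 3.34, 2.93 and 2.63, with no test. A lower noise estimate gave 259 calls and the absence of a detection filter gave 64.

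With stage as a block, the genotype comparison asked for a mean difference over the 3 stages, which need not be present at each. None of 12711 probes passed in limma (0 calls, smallest adjusted p = 0.383), with 1181 at an unadjusted p under 0.05. The smallest p-values among genes higher in mutants belonged to Ece1, the endothelin-converting enzyme gene (log2 difference 0.84 ± 0.04, SE, 3 pools against 3), Des (0.72 ± 0.04), C1qtnf2 (0.85 ± 0.05), Eif4ebp1 (1.11 ± 0.07), which encodes a repressor of translation, and Rpl13 (0.69 ± 0.05). Those among genes lower in mutants belonged to Fdps of the cholesterol pathway (−0.85 ± 0.04), the medium neurofilament gene Nefm (−1.01 ± 0.06), Ino80c (−0.56 ± 0.03), Stk39 (−0.55 ± 0.04) and Armc1 (−0.54 ± 0.04). All 10 had an adjusted p of 0.383 and do not pass. Each differed in the same direction at all 3 stages, which choosing the smallest p-values favours and which therefore adds no support. Rat Sod1 itself differed by −0.01 ± 0.12. Whether its probe reads the mutant transgene is not given in the sources used here, so its level checks no label.

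Among the lists, cholesterol synthesis had the smallest camera p across stages (median log2 difference −0.50, adjusted p = 1.17e-07), and 7 of its 18 genes fell when adjusted over the list alone, against 0 over all probes. Its presymptomatic median was −0.04, with 8 genes higher and 10 lower, so the difference lay at onset and end stage, and the onset and end-stage WT pools themselves stood at −0.51 and −0.54 from the presymptomatic WT pool. The interferon response (0.86, adjusted p = 2.38e-07), complement (1.09, adjusted p = 1.21e-05) and cytosolic ribosome lists (0.18, adjusted p = 4.99e-07) were higher. With stage as a block, 27 lists passed with the preset correlation, 16 higher and 11 lower, 17 without the end-stage WT pool, and 0 with an estimated correlation (smallest adjusted p = 0.573 with an estimated correlation).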

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

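The tests of the probe names, of array brightness, of the end-stage WT pool's part in the other patterns, of a difference lasting to onset or present at end stage and of splits by probe count were chosen only after the results were seen. Those of less muscle in the mutant pool and of splits by list count were written before. So was a test of array brightness by level in the presymptomatic WT pool, which met its bound against a dimmer array (median percentile 77.5 of all genes, bound 50) and decides nothing, since a 2-fold deficit needs a level of at least 7.63, above the median of all genes (7.19).

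There were 8 genes at least 2-fold higher in the mutant pool at end stage and at least 2-fold lower before symptoms, a difference between stages that was not tested. They were Col1a1 (−1.13 before symptoms, 2.02 at end stage, log2), S100a8 (−1.13 and 1.61), Plekha4 (−1.54 and 1.52), Pltp (−1.15 and 1.52), Gm2a (−1.19 and 1.42), Defa5 (−1.55 and 1.41), RT1-A1 (−1.91 and 1.34) and Col5a1 (−1.07 and 1.03). Plekha4, Gm2a, RT1-A1 and Col5a1 are named here because they make up this count, after their values were seen. Among 7326 genes counted at both stages, 289 were at least 2-fold higher at end stage and 208 at least 2-fold lower before symptoms. Independent lists of these sizes would share about as many, so 8 is no excess. All 8 belong to the 208 low presymptomatic transcripts weighed below, where a property of the RNA or array was left open.

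The first pattern weighed was the pairing of probe IDs with values. With the IDs sorted as text, 1.37% of sensory receptor probes were detected on all arrays, in line with an ID column that is in another order than the values. The same annotation table then gave 88.6% for ribosomal, respiratory chain and proteasome probes, which argues against wrong gene names in that table as the cause. No biological explanation was tested, and how the order arose stays open.

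The next was the low level of 208 transcripts in the presymptomatic mutant pool. At onset their median difference was −0.0403, inside the range of random lists (−0.10 to 0.00), so no genotype difference lasting from before symptoms to onset was seen. The onset mutant array had the highest median deposited intensity of the 6 (14.1, against 11.7 for its WT array). A lasting deficit could be hidden by such a difference between arrays, so the test does not exclude it. At end stage, however, they were lower in the mutant pool (median −0.35, random lists −0.14 to 0.02, 80.3% of them lower), and in the end-stage WT pool they were lower than in the onset WT pool (−0.25, random lists −0.02 to 0.08). A genotype difference present before symptoms and at end stage and a property of the RNA or array that the end-stage WT pool shares may therefore both contribute. Each of these differences sets 1 array against 1. The median deposited intensity was lowest on the presymptomatic mutant array (7.21). It was also lower on the end-stage mutant array (8.11) than on the end-stage WT array (9.75), though the former had more detected probes (10549 against 10122). A property of the array could thus also lie behind the end-stage deficit, and these values do not tell it from a genotype difference. Across probes the presymptomatic mutant array correlated more closely with the end-stage WT array (Pearson's r = 0.980) than with its own WT array (0.969). Of the 208, 93.3% (exact 95% interval 89.0 to 96.3%) were still detected in the presymptomatic mutant pool, but that need for a level above 7.63 left transcripts near background out of the count, so a dimmer array that loses transcripts near background stays open.

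The last was muscle. The muscle list was higher in the end-stage WT pool than in the other WT pools (median 0.80, random lists −0.08 to 0.13) and lower in the end-stage mutant pool than in those same WT pools (−0.69, random lists −0.17 to 0.19). Both muscle RNA in the end-stage WT pool and less of it in the mutant pool could therefore account for the end-stage difference. Tissue carried over at dissection and a difference in the animals were not tested against each other.

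The 6 pools can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split called 0 probes and passed 27 lists. The highest of the other splits also called 0 probes, so all 10 gave as many, and 3 of 10 splits passed as many lists, the highest other value being 27. In each of those other splits both presymptomatic pools stood on the same side, and so did both onset pools. With stage as a block, such a split compares only the end-stage mutant pool with its WT pool. It is therefore no separate grouping. Splits with a pool of every stage on both sides, other than the genotype split, passed 5, 6 and 21 lists. The count of lists thus decides nothing.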

How the results depend on the processing

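Added after seeing the data were the lower noise level from mid-range detection p, the WT pools of other stages as reference, the WT range limit, pools left out of the lists, and the IDs as deposited. The genotype test gave 0 calls in every alternative. All 213 end-stage calls kept their direction wherever tested, yet numbers moved and, unless the samples or genes used show it, the cause was not tested. The end-stage test gave 2 calls with the deposited normalized values, 550 with normexp at offset 50, 1056 with a 75th-percentile shift (446 higher, 610 lower, against 166 and 47), 415 with the lower noise level, 746 with a trended robust prior and 183 without background correction (163 and 20). Leaving out pools gave 0 to 213, with 0 whichever WT pool was left out, which leaves 1 residual degree of freedom while Atf3 kept 2.73 to 2.81. The onset test (0) gave 17 without background correction, 151 at offset 50, 666 with the shift, 86 with the lower noise level and 241 with the trended prior. In the same order the presymptomatic test (0) gave 254, 199, 393, 258 and 95, and end stage against presymptomatic (0) gave 103, 321, 877, 259 and 444, with 64 unfiltered and 63 without probes of a WT range of 2-fold or more. Genes differing 2-fold numbered 781, 353 and 862 (presymptomatic, onset, end stage) with the deposited values, 1075, 382 and 993 without background correction, 859, 333 and 814 with the lower noise level and 867, 569 and 1220 at 1.5-fold, against 238, 164 and 440, and at end stage 606 with the shift (225 higher, 381 lower, against 292 and 148). The presymptomatic count was 138 against the mean of the WT pools and 141 against the end-stage WT pool, and the onset count 363 against the presymptomatic and 317 against the end-stage WT pool. Lists passing across genotype, at end stage and at onset (27, 27 and 22) fell to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with the IDs as deposited, and across genotype to 17 without the end-stage WT pool. The presymptomatic lists (0) became 5 with the deposited values and 5 with the shift. Of 3208 alternatives for 230 results on named genes, 2679 gave the same call, 360 passed anew, 158 no longer passed and 11 reversed, all in end-stage differences that did not pass: Pmp22 (−0.0435 deposited, −0.00811 shift), Cd79b (0.0824, shift), Hoxb9 (0.0715, shift), Hoxc9 (0.0932, shift) and, with a pool left out, Mzb1 (−0.0077 to 0.0230), Defa5 (−0.0149 to 1.34), Np4 (−0.0497 to 0.712), Tekt4 (−0.0307 to 0.0488) and Cfap126 (−0.0318 to 0.0877). Of the 2679 same calls, 210, 200 and 60 came with the presymptomatic, onset and end-stage mutant pool left out. Leaving out a mutant pool cannot alter the test of another stage against the WT pools, so such calls add no support. The same holds for the end-stage calls kept with another mutant pool left out. Signal over background limits dim genes, and a BeadChip block was not run because the tables used give no chip. By replicate number no paired analysis was possible because each group holds 1 pool, and the genotype fit pairs pools by stage instead (0 calls with or without it).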

Other observations

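All lists here were fixed before the data were examined, whereas the fit of both symptomatic pools together and the lower noise level were chosen after the results were seen, and camera p-values are with the preset correlation by limma. T cell genes had an end-stage median of 0.08 over 12 genes (adjusted p = 0.00347, or adjusted p = 0.338 with an estimated correlation) or 0.68 with the lower noise level, and Cd8a rose by 0.81 on the log2 scale against the WT pools (adjusted p = 0.0337), beside Cd8b (0.39 against its WT pool), Cd3g (0.26) and Cd6 (0.21). The erythroid list was lower (median −0.20 over 7 genes, random lists −0.26 to 0.14, adjusted p = 0.0106, or adjusted p = 0.360 with an estimated correlation), with Hbb-b1 at −0.87 and Hbb at −0.36. Antioxidant and metal-binding genes did not pass as a list (median −0.03 over 32, adjusted p = 0.809), although the metallothionein gene Mt1 rose by 2.34 (adjusted p = 0.0303), Gpx3 stood at 1.20 and Sod2 at −0.97.

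Lists that did not pass at end stage also included heat shock chaperones (median −0.34 over 13 genes, adjusted p = 0.0543; Hspa2 1.17, Hspe1 −1.03), the unfolded protein response (−0.03 over 21, adjusted p = 0.540), oligodendrocyte precursors (−0.05 over 10, adjusted p = 0.657), endothelium and pericytes (0.01 over 12, adjusted p = 0.637), Schwann cells (0.33 over 5, adjusted p = 0.242), sensory ganglion (0.13 over 7, adjusted p = 0.0919; Scn10a 1.71, Calcb −1.16), neutrophils (0.15 over 10, adjusted p = 0.404; Lcn2 1.70), ependyma and choroid plexus (−0.01 over 8, adjusted p = 0.979) and reference genes (0.07 over 10, adjusted p = 0.698). Against all 3 WT pools, the contrast camera tests, the medians of reference (−0.03), endothelial (−0.01), ependymal (0.01) and unfolded protein response genes (0.03) had the other sign. With the lower noise level the medians were 1.22 for neutrophil and 0.48 for sensory ganglion genes. With a 75th-percentile shift the medians of the unfolded protein response (0.02), oligodendrocyte precursor (0.21), ependyma (0.26) and reference lists (−0.18) changed sign. Among reference genes, Gusb rose by 1.93 (adjusted p = 0.0435). Lists with fewer than 5 measured genes were not tested: 3 B cell genes (median 0.03), 1 lumbar Hox gene (Hoxd10, −0.49), 4 thoracic Hox genes (median −0.25) and 0 genes of the sex check.

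With the onset and end-stage mutant pools as 1 group against the WT pools, limma called 190 probes, 156 higher and 34 lower, of which 77 were also called at end stage alone. The genes that rose included Cd68 (4.45, adjusted p = 0.00790), Tyrobp (2.28, adjusted p = 0.00790), Lgals3 (3.53, adjusted p = 0.0240), Trem2 (2.42, adjusted p = 0.0273) and C1qb (2.28, adjusted p = 0.0446), while Atf3 (2.34, adjusted p = 0.0545) and Nefl (−1.0, adjusted p = 0.0592) did not pass.

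Microglial markers differed in size at end stage, and Gpnmb, P2ry12 and Sall1 here, like C1qb above, were chosen after their values were seen. Cd68 stood at 4.41, Fcrl2 at 2.15, Gpnmb at 0.93, P2ry12 at 0.05 and Sall1 at 0.01, and with the lower noise level at 4.28, 3.77, 2.64, 0.20 and 0.06. Of the 213 end-stage calls, 37 lay on probes without a name, 25 higher and 12 lower.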
